A study of Homo sapiens with 9 samples.

How the data were processed

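Total RNA from human umbilical vein endothelial cells at passage 5 was measured on 9 Agilent one-colour arrays, 3 for each of 3 groups: 24 h without nanoparticles, 24 h with nanoparticles and 7 d with nanoparticles. Per the labels, cells were expanded for 3 days, incubated for 4 h with 500 µg/mL of fluorescein-labelled nanoparticles or in medium alone, and returned to culture for 20 h or 7 d. The sort is stated for the labelled cells, and the labels do not say whether control cells went through the sorter. The series states independent experiments at each time, so an array was taken as the unit of replication. The labels do not describe the source of the cells or how the experiments were set up, and the p-values may therefore measure only the spread between these samples.

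Per the file headers, spot intensities were extracted by the authors with Feature Extraction 10.7.3.1. The processed intensity of each spot is background-subtracted and detrended within its array, with no normalization between arrays. The raw median spot and local background intensities and the background-subtracted intensity stand beside it in the deposited files. The deposited series table holds log2 values that equal the log2 of the background-subtracted intensity with a floor of 10, plus a constant on 2 of the 9 arrays (-0.027 and 0.016). The table lacks 1 to 9 values per array, and its medians lie between 6.36 and 6.64 on the log2 scale.

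Each array held 45015 spots, of which 43376 were not controls and carried 41000 probes. The files give no gene names, so the transcript accession of each probe was matched to a gene symbol in RefSeq. A symbol was found for 26222 probes, and 14778 probes were kept under their own accession or probe name. The arrays were annotated on hg19 and the RefSeq table on GRCh38.p14; only names were taken from it. Genes of X inactivation and of the Y chromosome (65 probes) were left out before any test. A probe was kept when it was well above background on all 3 arrays of at least 1 group, which left 29555 probes and 22461 genes, 14069 of them with a symbol. For the 5355 genes with several probes, the probe with the highest mean over all 9 arrays was used.

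The log2 of the processed intensity, less the 75th percentile of its array, was fitted in limma 3.58.1 (R 4.3.3) with 3 group means over all 9 arrays, followed by eBayes. The fit had 6 residual and 2.46 prior degrees of freedom and a median residual SD of 0.111 on the log2 scale. The 3 pairs of groups were compared, p-values were adjusted by Benjamini and Hochberg over all genes of a comparison, and genes with an adjusted p under 0.05 were called. A gene with no probe well above background on any array of a group is given as a bound, "at least N-fold", and without a fold when this held in both groups. Arrays above background were counted over all probes of a gene, while the change is that of its brightest probe. A plain fold can therefore come from a probe at background. Gene lists written before the data were examined, 32 of pathways and processes with at least 5 measured members, were tested with camera at a preset correlation of 0.01, two-sided, and adjusted over the lists. Camera compares the changes of a list with those of all other genes, so its direction is relative to them. Camera with an estimated correlation and fry, which tests whether the genes of a list move one way on balance, were run as alternatives, and 7 lists of cell type markers were counted without a test.

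The named genes follow a rule fixed before the data were examined. For each comparison it takes the called genes with a symbol whose 3 arrays of a group all lie above the 3 of the other, 12 with the largest rise and 12 with the largest fall. For each list described it takes up to 4 called members with the smallest p, or 2 where none is called. For the overlap of the comparisons against the control it takes 6 genes per direction with the largest smaller change. MORN3, HAPLN2, PLPPR3 and H2AC1, which the rule also takes, lost their 24 h call under most of the arrays left out, and are not described further.

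The fit was tested on simulated data with the spread of these arrays, in which 200 genes were changed. In the 24 h comparison 0% of 67 genes changed by 0.25 on the log2 scale were recovered, 40.3% of 67 changed by 0.5 and 86.4% of 66 changed by 1, with 6 calls among unchanged genes and 0 calls by camera among unchanged lists. The simulation gave 90 calls in all, against 3993 in the data, so its adjusted threshold was stricter and these shares do not carry over. Its genes were drawn independently, so the 0 list calls do not cover lists whose genes move together. Signal over background and the number of arrays limit the precision of each value. Alternatives were normexp background correction with an offset of 50, quantile normalization, median centring, no filter and a filter on all 9 arrays, the mean over probes, all probes, the deposited log2 values, a fit of the 6 arrays compared, an intensity trend in eBayes, the replicate number as a block, and leaving out each array in turn. Normexp was run on the median spot intensity, since the deposited files hold no mean spot intensity. Cyclic loess between arrays and random lists matched on brightness were added after the data were seen. Slide as a block could not be run, since 0 of the 3 slides held arrays of more than 1 group. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.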

Results

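Gene expression was measured in human umbilical vein endothelial cells (HUVECs), primary cells that line the umbilical vein, on 9 one-colour microarrays. The arrays fell into 3 groups of 3: cells kept without nanoparticles and collected at 24 h, cells loaded with fluorescent nanoparticles and collected at 24 h, and loaded cells collected at 7 d. Loaded cells had taken up the particles during 4 h at 500 µg/mL and had been collected by fluorescence-activated sorting. The labels did not give the composition of the particles. The deposited series held no 7 d group without nanoparticles, so a difference at 7 d held time in culture and nanoparticles together. Changes are on the log2 scale with the standard error of the fit and 3 arrays per group, and the 3 arrays of each group are all the replication behind them.

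The share of probes above background was close in the 3 groups, while the strength of the signal was lower at 7 d. Before scaling, the 75th percentile of the processed intensity was 780 to 850 on the 24 h arrays without nanoparticles. It was 722 to 811 on those with nanoparticles and 669 to 707 on the 7 d arrays. Between 71.4% and 72.7% of the probes were well above background on the 24 h arrays without nanoparticles, between 68.6% and 69.9% on the 24 h arrays with nanoparticles and between 72.0% and 74.0% on the 7 d arrays. The negative control spots carried a net signal of 22.4 to 23.9, 21.6 to 23.9 and at most 11.4 intensity units in the 3 groups, in that order. The first principal component held 75.3% of the variance. It parted the 7 d arrays, at 73.1 to 79.5, from the 24 h arrays with nanoparticles, at -51.1 to -46.9, and those without, at -29.3 to -22.5. The second, with 9.2% of the variance, parted the 24 h groups, at 24.0 to 26.8 without nanoparticles and -23.5 to -15.0 with them. Each group had been hybridised on its own slide, so slide and group cannot be told apart in any comparison.

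**Figure D1:**
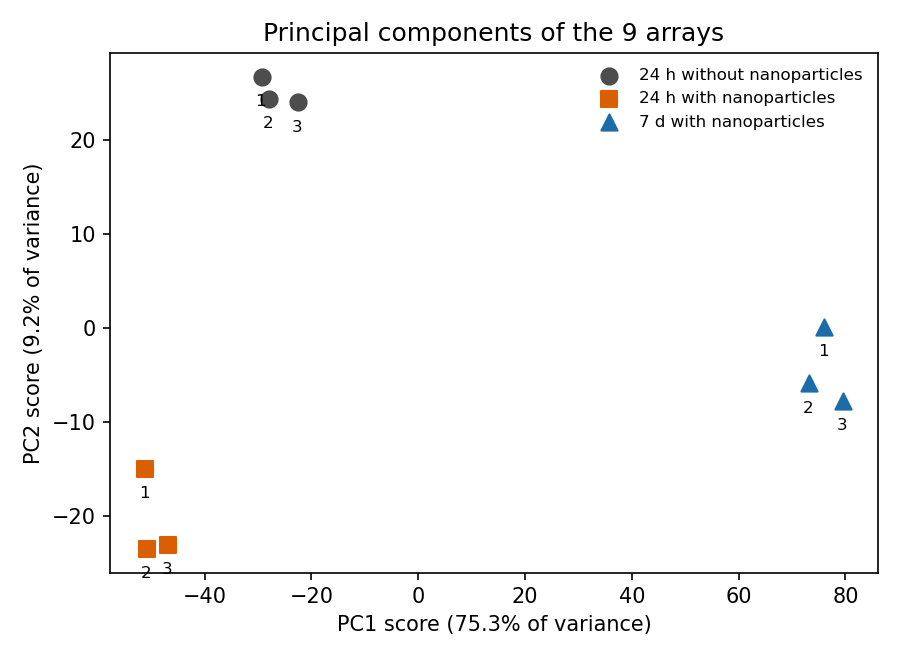
Scores of the 9 arrays on the first principal component (x axis, 75.3% of the variance) and the second (y axis, 9.2%), from scaled log2 signals of 22461 genes. Each point is an array, coloured by group and numbered by replicate; the 7 d arrays lie at 73.1 to 79.5 on the x axis and all 24 h arrays below 0.

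At 24 h, loaded cells were compared with cells kept without nanoparticles, the only groups matched for time. Genes of cholesterol synthesis were higher in the loaded cells, with 21 of 25 measured members called higher and a median change of 0.59. ACAT2 rose by 0.91 ± 0.07 and HMGCS1, an early enzyme of the pathway, by 0.84 ± 0.08. DHCR7, which carries out a last step of it, rose by 0.82 ± 0.08 and TM7SF2 by 0.62 ± 0.06. Adjusted over the list alone, 22 members were higher. The list passed camera (adjusted p = 1.82e-22; adjusted p = 0.102 with an estimated correlation). Its median lay 0.617, 0.603 and 0.549 above the control mean on the 3 loaded arrays. Genes of fatty acid synthesis, lipid storage and the sterol-sensing receptor LXR moved in both directions, with 5 of 23 higher and 3 lower (adjusted p = 0.0166; adjusted p = 0.305 with an estimated correlation). FADS2, a fatty acid desaturase, rose by 0.68 ± 0.08. ABCG1, a sterol exporter, changed by -0.68 ± 0.08, MYLIP, which marks the LDL receptor for breakdown, by -0.38 ± 0.06 and PDK4 by -1.14 ± 0.14. In this list 8 genes were higher and 5 lower when adjusted over the list alone. Its call was lost with fry (adjusted p = 0.058), with quantile normalization (camera, adjusted p = 0.0575) and without control replicate 2 (camera, adjusted p = 0.0711).

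Cell cycle genes parted by phase. Of 33 measured genes of the G1/S transition and DNA replication, 14 rose, with a median change of 0.23 (camera, adjusted p = 1.1e-12; adjusted p = 0.305 with an estimated correlation). Among them were ORC1 (0.63 ± 0.07), UHRF1 (0.45 ± 0.07), CDC6 (0.43 ± 0.07) and CHAF1A (0.33 ± 0.06). Of 33 genes of G2/M and mitosis, 14 fell and 1 rose, with a median of -0.22 (adjusted p = 0.00018; adjusted p = 0.305 with an estimated correlation). The mitotic motor KIF20A changed by -0.67 ± 0.07, the kinase PLK1 by -0.51 ± 0.07, CENPA by -0.50 ± 0.08 and cyclin B1 (CCNB1) by -0.43 ± 0.07. When adjusted over the list alone, 20 replication genes were higher, and 18 mitotic genes were lower and 2 higher.

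**Figure D2:**
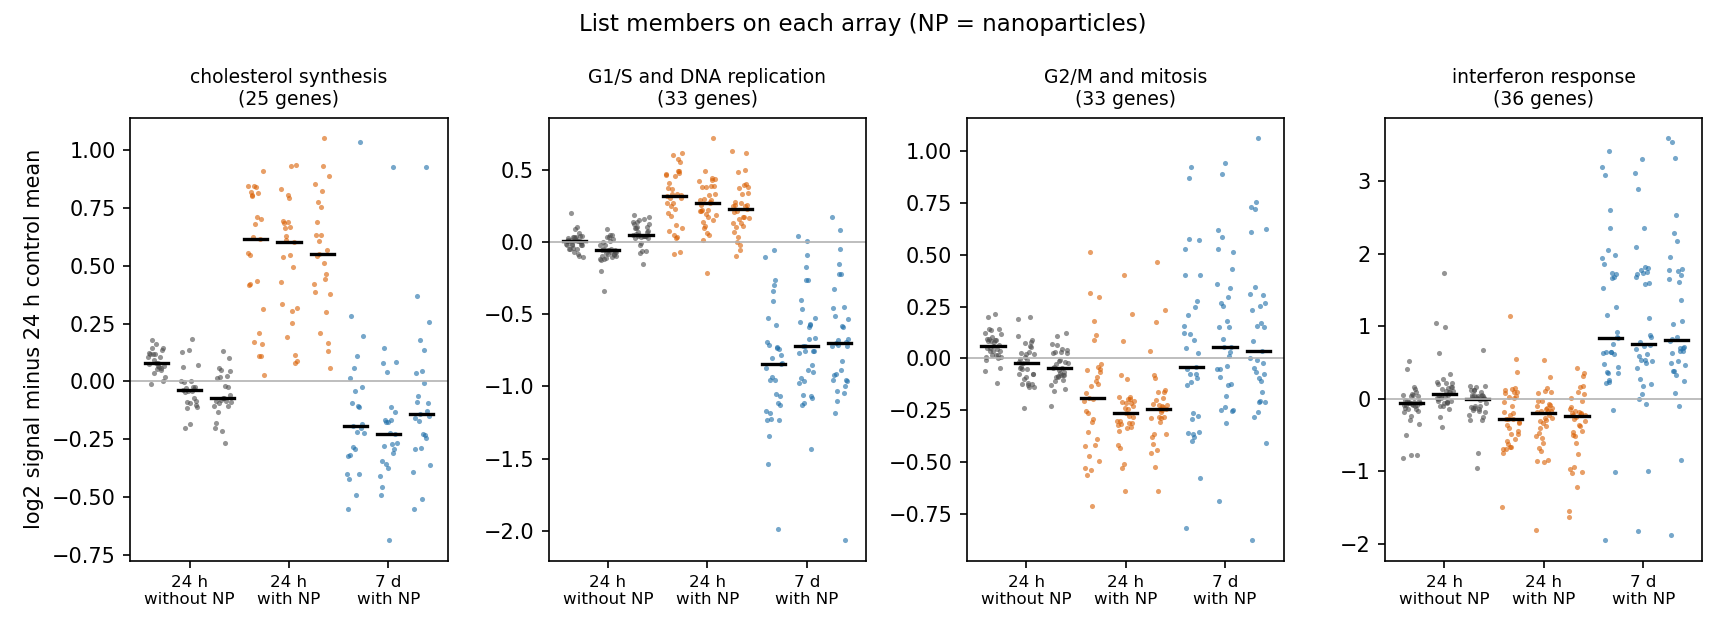
Log2 signal minus the mean of the 24 h arrays without nanoparticles (y axis) for members of the cholesterol synthesis, G1/S, G2/M and interferon response lists, on each of the 9 arrays by group; a point is a gene and a bar the median of the list on that array. Median cholesterol synthesis genes lay at 0.549 to 0.617 on the loaded 24 h arrays and at -0.228 to -0.141 at 7 d, and median interferon response genes at -0.274 to -0.198 and at 0.761 to 0.843.

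Interferon response genes fell at 24 h, with 12 of 36 members lower and a median of -0.24 (camera, adjusted p = 0.0093; adjusted p = 0.305 with an estimated correlation). IFIT3 changed by -0.84 ± 0.11, XAF1 by -0.80 ± 0.12 and IFI6 by -0.63 ± 0.08, and IFIT2 was at least 1.71-fold lower. Of these, IFIT3, XAF1 and IFIT2 lost their call when the median spot intensity with normexp correction and an offset replaced the scanner's processed intensity. Among all members, 14 were lower and 1 higher when adjusted over the list alone. Without control replicate 2 the list was not called (adjusted p = 0.075). Inflammatory NF-kB targets were not called as a list (3 of 28 higher, 8 lower; camera, adjusted p = 0.519). Fry called this list lower (adjusted p = 0.0372). The chemokine CXCL8 changed by -1.13 ± 0.16 and CXCL3 by -0.55 ± 0.08, TNF was at least 1.5-fold lower, and the chemokine CCL2 rose by 0.70 ± 0.11. Markers of other cell types moved alongside, and their called members were named after their values were seen. Of 9 leukocyte markers, 6 fell, CD14 among them (-0.45 ± 0.10), and ITGB2 rose. Of 6 lymphatic markers, PROX1 (-0.77 ± 0.12), LYVE1 (-1.86 ± 0.14) and ITGA9 (-0.50 ± 0.09) fell. The smooth muscle markers ACTA2 and LMOD1 (2 of 7), the fibroblast marker DCN (1 of 6), the epithelial markers KRT14 and ESRP1 (2 of 4) and the erythroid markers HBA1, HBA2 and ALAS2 (3 of 3) also fell. Among the venous markers limma called 0 of 4 (0 at an unadjusted p under 0.05). Set against random lists matched on brightness, the medians lay at percentiles 1.44 (lymphatic), 2.84 (leukocyte), 4.9 (erythroid) and 7.64 (smooth muscle). Those of the epithelial, venous and fibroblast markers lay at 11.9, 28.55 and 29.1, so they did not stand apart from genes as bright.

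Of 23 targets of NRF2, the regulator of the oxidative stress response, 6 rose, with a median of 0.13 (camera, adjusted p = 6.42e-06; adjusted p = 0.0479 with an estimated correlation). The members with the smallest p were the pentose phosphate enzymes PGD (0.55 ± 0.11) and TKT (0.29 ± 0.05), the quinone reductase NQO1 (0.31 ± 0.06) and ME1 (0.25 ± 0.05). The other 17 were not called, among them HMOX1, whose change was the lowest of the list (-0.09). Among 12 metallothioneins and zinc carriers 3 rose (camera, adjusted p = 0.00177; adjusted p = 0.348 with an estimated correlation). MT1F, a metal-binding protein whose sequence is close to that of its relatives, rose 3.89-fold (1.96 ± 0.10), while the list's median change was 0.06. The other called members were the zinc exporter SLC30A1 (0.30 ± 0.07) and MT1M (0.23 ± 0.06). The call of SLC30A1 was lost without control replicate 2, loaded replicate 2 or loaded replicate 3 (adjusted p = 0.0569, 0.0676 and 0.0689), and that of MT1M without any one of the 6 arrays (adjusted p = 0.0586 to 0.0929). Of 30 genes of extracellular matrix and basement membrane, 6 rose and 2 fell (camera, adjusted p = 0.00172; adjusted p = 0.305 with an estimated correlation). The elastic fibre protein FBLN5 rose by 0.84 ± 0.06 and the collagens COL12A1 and COL8A1 by 0.77 ± 0.07 and 0.64 ± 0.07, while elastin (ELN) changed by -0.63 ± 0.08 on its brightest probe and by -0.08, without a call, as the mean of its probes. In these lists, 7 NRF2 targets and 3 metallothioneins were higher when adjusted over the list alone, and 7 matrix genes were higher and 3 lower.

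Lysosomal genes passed camera with 3 of 35 members higher and 1 lower (median 0.02; adjusted p = 0.0139; adjusted p = 0.305 with an estimated correlation), and the same numbers were called when adjusted over the list alone. The median lay at percentile 51.5 of 10000 random lists matched on brightness. That list's call ended with quantile normalization (adjusted p = 0.147) and without control replicate 2 (adjusted p = 0.0532). Its members NPC1, IDS and NEU1 changed by 0.38 ± 0.09, 0.37 ± 0.08 and 0.24 ± 0.06, and the protease CTSK by -0.30 ± 0.07. Without control replicate 1 neither NPC1 (adjusted p = 0.0639), IDS (0.0606) nor NEU1 (0.0565) was called, and NPC1 and NEU1 were not called either without control replicate 3 (0.0809 and 0.0558), loaded replicate 2 (0.0513 and 0.0715) or loaded replicate 3 (0.0664 and 0.0504). Cytosolic ribosomal proteins passed camera at a median of 0.05 (adjusted p = 0.00177; adjusted p = 0.664 with an estimated correlation), while limma called 0 of 50 members, 0 at an unadjusted p under 0.05 and 0 adjusted over the list alone. The ribosomal call was lost with fry (adjusted p = 0.461), with quantile normalization (0.43) and without control replicate 2 (0.133) or loaded replicate 1 (0.227). Lists without a call included autophagy, where limma called 0 of 26 genes (5 higher and 1 lower at an unadjusted p under 0.05; camera, adjusted p = 0.0564), and apoptosis regulators (2 of 26 higher, 1 lower; adjusted p = 0.299). Camera did not call the chaperones of the unfolded protein response (2 of 20 lower, adjusted p = 0.232) or of heat shock (1 of 20 higher, 1 lower, adjusted p = 0.1). Nor did it call p53 targets (5 of 24 lower), cytokine and senescence-associated secretion (9 of 23 lower, 1 higher) or metalloproteinases and inhibitors (6 of 20 lower). Fry called all of these but heat shock lower (adjusted p = 0.0469, 0.00232, 0.000989 and 0.000539), and junctions higher (0.0287). Against lists matched on brightness, the medians of those lower by fry lay at percentiles 0.11, 0.37, 0.02 and 4.07. Endothelial identity genes were not called as a list either (3 of 32 higher, 3 lower; adjusted p = 0.825). Median, mean and test differed in sign for that list and for those of apoptosis regulators, oxidative phosphorylation, endocytosis, coagulation, immediate early genes and TGF-beta. The direction of camera is relative to the other genes, and the median change of all genes tested was -0.03. A camera call at 24 h is therefore not by itself a change of the list against the control.

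Single genes were ranked among those with all 3 arrays of a group above all 3 of the other. Among the largest rises after MT1F were those in OLFML2A (at least 2.49-fold), SEMA7A (1.44 ± 0.25, above background on 1 of the 3 control arrays) and CLEC3B (2.54-fold). The tight junction protein CLDN14 (2.3-fold) and the small heat shock protein CRYAB (2.13-fold) were also among the largest. HAO1, COMP and ADRB1 were at least 1.75-fold, 1.81-fold and 1.73-fold higher, and normexp correction ended these 3 calls. Among the largest falls were those in the Wnt inhibitor APCDD1 (-2.89 ± 0.35, above background on 1 of the 3 loaded arrays), SPON2 (6.57-fold lower) and the phosphatase ACP5 (4.74-fold lower). They were followed by the imprinted non-coding RNA H19 (-2.09 ± 0.18, above background on 1 loaded array), CCDC178 (3.85-fold lower) and the hyaluronan receptor LYVE1 (3.62-fold lower). SEMA6A was 3.67-fold lower on its brightest probe, while its probe above background on all 9 arrays changed by -0.10 and was not called. The retinoic acid hydroxylase CYP26B1 was at least 1.87-fold lower, a call that the deposited log2 values did not give, and SLAMF8 was at least 1.7-fold lower.

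Over all 22461 genes, limma called 736 higher and 3257 lower at 24 h, of which 15 and 285 changed at least 2-fold. The share called higher was 18.4%, against 32.7% with quantile normalization and 34.4% with cyclic loess. Calls that were lower made up 94.4% of the calls among the 7487 dimmest genes, whose median change was -0.22, and 53.7% among the 7487 brightest. Quantile normalization called 1922 genes lower. The 2-fold counts of 15 and 285 became 5 and 8 with normexp correction, 36 and 102 with quantile normalization, 52 and 81 with cyclic loess and 7 and 74 with the filter on all 9 arrays. The count of 15 became 23 without the filter and 32 without control replicate 1, and that of 285 became 110 with the deposited log2 values. Without control replicate 1, control replicate 3, loaded replicate 2 or loaded replicate 3, the count of 736 became 435, 469, 481 or 446, and the 10 called lists became 6 without control replicate 2.

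**Figure D3:**
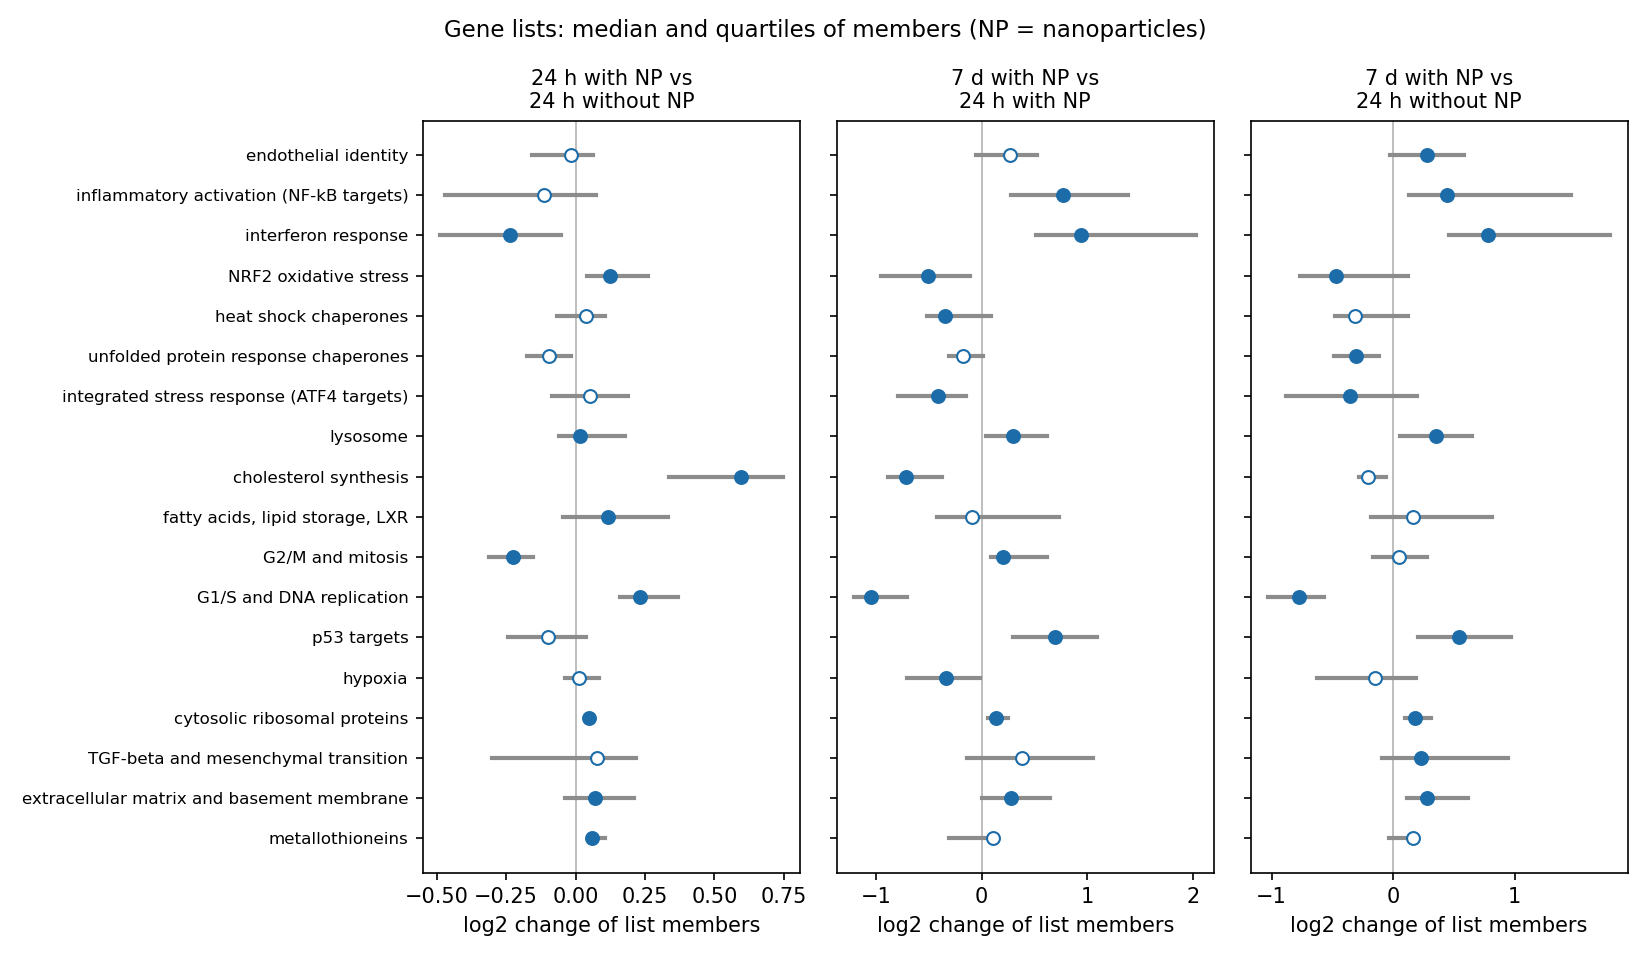
Log2 change of the members of the 18 of 32 gene lists that camera called in any comparison (x axis) in the 3 comparisons, a panel each; points are list medians, filled where camera called the list, and bars run from the lower to the upper quartile. Cholesterol synthesis has a median of 0.59 at 24 h and -0.72 between 24 h and 7 d, and the G1/S list 0.23 and -1.05.

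Loaded cells at 7 d were next compared with loaded cells at 24 h. Interferon response genes rose almost throughout the list, with 34 of 36 higher and 2 lower and a median of 0.94. IFI44L rose by 3.84 ± 0.13, IFIT3 by 2.45 ± 0.11 and IFITM1 by 1.98 ± 0.08 (camera for the list, adjusted p = 3.02e-07; adjusted p = 0.146 with an estimated correlation). Of 28 inflammatory NF-kB targets, 21 rose and 1 fell, with a median of 0.77 (adjusted p = 0.000557; adjusted p = 0.275 with an estimated correlation). The cytokine IL33 rose 71.7-fold (6.16 ± 0.26, above background on 2 of the 3 loaded 24 h arrays), CXCL3 by 2.07 ± 0.08, CCL2 by 1.99 ± 0.11 and the adhesion molecule ICAM1 by 1.64 ± 0.08. Of 24 p53 targets, 18 rose and 1 fell, with a median of 0.70 (adjusted p = 5.93e-05; adjusted p = 0.0947 with an estimated correlation), among them BTG2 (1.97 ± 0.05), TNFRSF10C (1.44 ± 0.06) and SESN1 (1.26 ± 0.07). By list, 34 interferon genes were higher and 2 lower when adjusted over the list alone, 21 inflammatory genes were higher and 1 lower, and 19 p53 targets were higher and 1 lower.

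DNA replication and sterol synthesis genes moved the other way. Of 33 G1/S genes, 31 fell, with a median of -1.05 (camera, adjusted p = 1.21e-11; adjusted p = 0.275 with an estimated correlation), CDC6 by -1.58 ± 0.07, UHRF1 by -1.55 ± 0.07 and RFC4 by -1.29 ± 0.07. Of 25 cholesterol synthesis genes, 23 fell and 1 rose, with a median of -0.72 (adjusted p = 3.02e-07; adjusted p = 0.275 with an estimated correlation). HMGCS1 changed by -1.37 ± 0.08 and ACAT2 by -1.10 ± 0.07. NRF2 targets fell in 16 of 23 cases and rose in 3 (median -0.51; adjusted p = 0.000871; adjusted p = 0.0947 with an estimated correlation), with the haem-degrading enzyme HMOX1 at -1.46 ± 0.11, SRXN1 at -1.20 ± 0.05 and NQO1 at -1.12 ± 0.06. Targets of ATF4 in the integrated stress response fell in 17 of 26 cases and rose in 6 (median -0.41; adjusted p = 0.0153; adjusted p = 0.375 with an estimated correlation), with the amino acid transporter SLC7A5 at -1.54 ± 0.10 and DDIT4 at 1.68 ± 0.06. In the G1/S list 32 genes were lower when adjusted over the list alone, and the counts of the other lists were as given.

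Lysosomal genes rose in 23 of 35 cases and fell in 5, with a median of 0.30 (camera, adjusted p = 0.0168; adjusted p = 0.275 with an estimated correlation), among them GPNMB (1.64 ± 0.08), MANBA (1.09 ± 0.09) and the membrane protein LAMP2 (0.86 ± 0.05). Mitotic genes rose in 17 of 33 cases and fell in 3 (median 0.20; adjusted p = 0.0405; adjusted p = 0.532 with an estimated correlation), with KIF20A at 1.64 ± 0.07 and CCNB1 at 1.06 ± 0.07. Matrix genes rose in 17 of 30 cases and fell in 2 (median 0.28; adjusted p = 0.0454; adjusted p = 0.375 with an estimated correlation), with COL12A1 at 1.30 ± 0.07 and the basement membrane protein NID2 at -2.20 ± 0.09. Hypoxia genes fell in 14 of 25 cases and rose in 6 (adjusted p = 0.0433; adjusted p = 0.375 with an estimated correlation). Heat shock chaperones fell in 13 of 20 and rose in 2 (adjusted p = 0.0448; adjusted p = 0.275 with an estimated correlation). Cytosolic ribosomal proteins rose in 22 of 50 cases and fell in 1 (adjusted p = 0.0433; adjusted p = 0.767 with an estimated correlation), and their direction turned with quantile normalization (adjusted p = 0.835). The counts of these 6 lists were the same when adjusted over the list alone. The calls of the mitotic, hypoxia, heat shock, matrix and ribosomal lists were lost with median centring (adjusted p = 0.0501 to 0.0965), without loaded 24 h replicate 2 (0.0542 to 0.133) and without 7 d replicate 2 (0.0608 to 0.114). Quantile normalization also ended those of the hypoxia (0.08) and heat shock (0.0556) lists. Those of the hypoxia, heat shock, matrix and ribosomal lists were lost without loaded 24 h replicate 3 (0.0532 to 0.102), and that of the matrix list without 7 d replicate 1 (0.0751). Markers of other cell types moved with these groups and were named after their values were seen. Of 6 fibroblast markers, COL1A2, COL3A1, DCN, FAP and THY1 rose, and of 6 lymphatic markers, PROX1, LYVE1, FLT4, CCL21 and ITGA9. Of 7 smooth muscle markers, ACTA2, CNN1 and LMOD1 rose and SMTN fell, and of 9 leukocyte markers 6 rose and CD68 and LAPTM5 fell. The epithelial markers KRT14 and ESRP1 rose and KRT19 fell, the venous markers EPHB4 and FLRT2 rose and NR2F2 fell, and the erythroid markers HBA1 and ALAS2 rose. Set against random lists matched on brightness, the lymphatic median lay at percentile 97.5 and the venous at 92.2. The leukocyte, fibroblast, epithelial, erythroid and smooth muscle medians lay at 86.0, 73.2, 67.4, 58.7 and 58.55, and did not stand apart from genes as bright.

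Among the largest rises between 24 h and 7 d after IL33 were those in the water channel AQP1 (69.8-fold, 6.13 ± 0.18), the death ligand TNFSF10 (44-fold) and the arterial gap junction protein GJA4 (38.2-fold). Next came FILIP1 (35.7-fold, above background on 1 of the 3 loaded 24 h arrays) and the chemokine-scavenging receptor ACKR4 (29-fold). GALNT15, the sterol exporter ABCA1, CYP26B1, the serotonin receptor HTR2B and the fatty acid transporter CD36 were at least 27.3-fold, 15.3-fold, 13-fold, 12.4-fold and 7.79-fold higher. Among the largest falls were those in FCMR (63.5-fold, -5.99 ± 0.50) and the synaptic protein NPTX1 (-4.67 ± 0.23, above background on 1 of the 3 arrays at 7 d). CRYAB fell 13.8-fold, as did PMCH, whose copy PMCHL1 is close to it in sequence (13.6-fold). LCN6, CDCP1, ANO1, STATH and IL13RA2 were at least 9.6-fold, 9.54-fold, 3.48-fold, 3.43-fold and 3.31-fold lower. Over all genes, limma called 8203 higher and 7252 lower, of which 2767 and 1068 changed at least 2-fold. The direction varied with brightness here too. Lower calls made up 31.1% of the calls among the 7487 dimmest genes, whose median change was 0.32. Among the 7487 brightest they made up 60.4%, with a median change of -0.09. A trend with brightness between the slides may therefore account for part of these counts. The 2-fold counts became 1097 and 398 with normexp correction, and the 13 called lists became 8 without loaded 24 h replicate 2, 8 without 7 d replicate 2, 8 with median centring and 10 with quantile normalization.

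Set against the 24 h cells without nanoparticles, loaded cells at 7 d were again higher in interferon, inflammatory and p53 genes. Of 36 interferon genes, 31 rose and 2 fell, with a median of 0.78 (camera, adjusted p = 2.8e-07; adjusted p = 0.138 with an estimated correlation). IFI44L rose by 3.35 ± 0.13, while ISG20 changed by -1.88 ± 0.09. Of 28 inflammatory genes, 18 rose and 1 fell, with a median of 0.44 (adjusted p = 0.000412; adjusted p = 0.225 with an estimated correlation), with CCL2 at 2.69 ± 0.11 and ICAM1 at 1.52 ± 0.08. Of 24 p53 targets, 18 rose, with a median of 0.54 (adjusted p = 1.51e-05; adjusted p = 0.0693 with an estimated correlation), BTG2 by 1.61 ± 0.05 and FDXR by 0.96 ± 0.06. Of 33 G1/S genes, 30 fell, with a median of -0.77 (adjusted p = 6.46e-09; adjusted p = 0.315 with an estimated correlation). Cholesterol synthesis was not called (2 of 25 higher, 14 lower; median -0.20; adjusted p = 0.104), with HMGCS1 at -0.53 ± 0.08 and TM7SF2 at 0.96 ± 0.06. For each list in turn, 31 interferon genes were higher and 2 lower when adjusted over the list alone, 19 inflammatory genes were higher and 1 lower, and 19 p53 targets were higher. In the other lists 30 G1/S genes were lower, and 3 cholesterol synthesis genes were higher and 14 lower.

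Lysosomal genes rose in 24 of 35 cases and fell in 4 (median 0.35; camera, adjusted p = 0.000412; adjusted p = 0.138 with an estimated correlation), with GPNMB at 1.84 ± 0.08, the hexosaminidase subunit HEXA at 1.03 ± 0.07 and LAMP2 at 0.98 ± 0.05. Endothelial identity genes rose in 19 of 32 cases and fell in 6 (median 0.28; adjusted p = 0.0387; adjusted p = 0.217 with an estimated correlation). CD34 rose by 2.23 ± 0.13 and the transcription factor FLI1 by 0.84 ± 0.05, while PLVAP, a protein of fenestral diaphragms, changed by -2.49 ± 0.09 and the angiopoietin receptor TEK by -0.89 ± 0.06. Matrix genes rose in 16 of 30 cases and fell in 2 (adjusted p = 0.00167; adjusted p = 0.269 with an estimated correlation), with COL12A1 at 2.06 ± 0.07. Genes of TGF-beta and mesenchymal transition rose in 16 of 28 cases and fell in 4 (adjusted p = 0.0436; adjusted p = 0.315 with an estimated correlation), with TGFB2 at 2.34 ± 0.10 and ACTA2 at 1.18 ± 0.06. Beside these, the fibroblast markers COL1A2, COL3A1 and FAP (3 of 6) rose, and FBLN1 was lower on its brightest probe while another of its probes was called higher. The smooth muscle markers ACTA2, CNN1 and RGS5 (3 of 7) rose and SMTN fell, and the markers of all these cell types were named after their values were seen. Of 9 leukocyte markers, ITGAM, ITGB2 and FCER1G rose and CD68, CD3E and LAPTM5 fell. The lymphatic markers PROX1 and FLT4 rose and LYVE1 fell, the venous markers EPHB4 and FLRT2 rose and NR2F2 fell, the epithelial markers KRT14 and ESRP1 rose and EPCAM and KRT19 fell, and the erythroid marker ALAS2 rose. Set against random lists matched on brightness, the venous, fibroblast and lymphatic medians lay at percentiles 93.6, 85.3 and 84.1. The epithelial, leukocyte, smooth muscle and erythroid medians lay at 48.9, 33.5, 30.15 and 26.1.

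Chaperones of the unfolded protein response fell in 13 of 20 cases and rose in 1 (median -0.30; camera, adjusted p = 0.011; adjusted p = 0.315 with an estimated correlation), with SDF2L1 at -1.18 ± 0.10 and HSPA5, the main chaperone of the endoplasmic reticulum, at -0.85 ± 0.13. ATF4 targets fell in 17 of 26 cases and rose in 4 (adjusted p = 0.0387; adjusted p = 0.416 with an estimated correlation), with ASNS at -1.74 ± 0.12. NRF2 targets fell in 14 of 23 cases and rose in 4 (adjusted p = 0.0387; adjusted p = 0.217 with an estimated correlation), with HMOX1 at -1.55 ± 0.11. Cytosolic ribosomal proteins rose in 26 of 50 cases (median 0.18; adjusted p = 0.000412; adjusted p = 0.686 with an estimated correlation). The counts for the lists in this paragraph and for the lysosome, endothelial, matrix and TGF-beta lists were the same when adjusted over the list alone. Quantile normalization ended the calls of ribosomal proteins, endothelial identity, NRF2 targets, ATF4 targets and TGF-beta, which left 7 of the 12 called lists. Omitting control replicate 2 ended those of NRF2 targets and TGF-beta (adjusted p = 0.0511 and 0.0738), and omitting control replicate 3 or 7 d replicate 2 ended those of ATF4 targets (0.0721 and 0.0502) and TGF-beta (0.0646 and 0.055).

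Among the largest rises against the 24 h control were those in AQP1 (48.4-fold), IL33 (38.8-fold), GJA4 (26.1-fold) and ACKR4 (20-fold). The prostacyclin synthase PTGIS (4.25 ± 0.29, above background on 1 of the 3 control arrays), TNFSF10 (15.7-fold) and the fatty acid-binding protein FABP4 (3.94 ± 0.33, above background on 2 control arrays) followed, and HTR2B and CD36 were at least 13.5-fold and 8.43-fold higher. Among the largest falls were those in FCMR (99.2-fold, -6.63 ± 0.50), NPTX1 (-5.74 ± 0.23, above background on 1 of the 3 arrays at 7 d), PI16 (15-fold) and the matricellular protein CCN3 (13.9-fold). LCN6, CDCP1 and STATH were at least 17.2-fold, 13.9-fold and 6.1-fold lower. Among coagulation genes, a list that camera did not call (adjusted p = 0.696), SERPINB2 changed by -3.28 ± 0.06 and tissue plasminogen activator (PLAT) by -1.96 ± 0.07. Over all genes, limma called 6842 higher and 7194 lower, of which 1646 and 970 changed at least 2-fold. Lower calls made up 44.7% of the calls among the 7487 dimmest genes and 57.9% among the 7487 brightest. The 2-fold counts became 799 and 293 with normexp correction.

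The last question was whether the genes that moved at 24 h were also away from the control at 7 d. Of the 3257 genes lower at 24 h, 1691 were higher and 490 lower at 7 d, where independent calls would give 992 and 1043. Of the 736 genes higher at 24 h, 304 were lower and 230 higher at 7 d, where independent calls would give 236 and 224. CRYAB (1.09 ± 0.08 and -2.70 ± 0.08), the drug exporter ABCC3 (0.89 ± 0.12 and -2.28 ± 0.12) and CLDN14 (1.20 ± 0.08 and -1.39 ± 0.08) were higher at 24 h and lower at 7 d. CCDC178 (-1.95 ± 0.08 and 1.98 ± 0.08), MS4A6A (-1.54 ± 0.16 and 2.50 ± 0.16) and the retinol-metabolising enzyme DHRS3 (-1.50 ± 0.10 and 2.26 ± 0.10) were lower at 24 h and higher at 7 d. SPON2 (-2.72 ± 0.23 and -3.19 ± 0.23) and ACP5 (-2.24 ± 0.10 and -2.50 ± 0.10) were lower at both times, while FBLN5 (0.84 ± 0.06 and 1.08 ± 0.06) and OLFML2A, at least 2.49-fold and 4.09-fold, were higher at both. Across the 22461 genes, which are not independent replicates, the changes correlated at r = -0.175 and rho = -0.223. Simulated unchanged groups sharing the 3 control arrays gave r = 0.495 and 0 shared calls by limma. Groups without change leave little to call, so the 0 gives no expected number of shared calls. The covariance was -0.041, against 0.0108 in the simulation. With 3 controls, giving each comparison its own would leave 1 of them with a single control array, so the overlap was not counted that way, and part of the calls in the same direction may come from the shared arrays. In all, 720 genes moved the same way and 1995 the opposite way. Without control replicate 1 the count of 720 became 444, and without control replicate 3 that of 1995 became 1315.

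**Figure D4:**
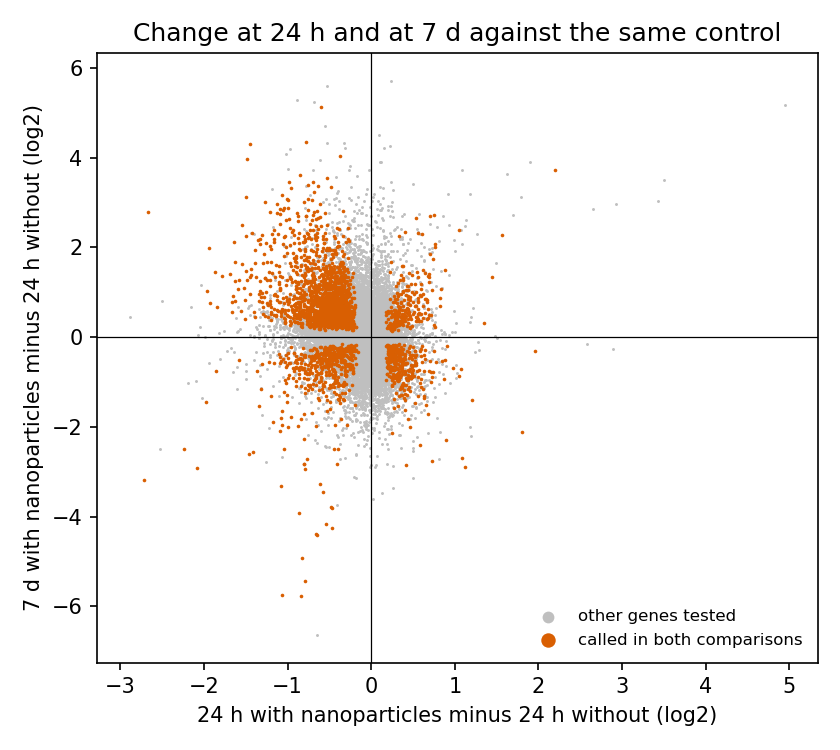
Log2 change of each of 22461 genes at 24 h with nanoparticles (x axis) against its change at 7 d with nanoparticles (y axis), both relative to the 24 h cells without nanoparticles. The 1995 genes called in both with opposite directions and the 720 with the same direction are orange, all others grey; r = -0.175 over all genes.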

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

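Cyclic loess and the lists matched on brightness were chosen after seeing the data, and all other alternatives before. Slide as a block could not be run, since each slide held 1 group. Of 3967 values of 237 named gene results under the alternatives, 3877 kept their direction and their side of the threshold, 89 were no longer called and 1 reversed, TTC39A at 24 h with the deposited log2 values (0.041), where it lay below background in both groups. At 24 h, normexp correction ended 12 of the calls on named genes, the fit of 6 arrays 9, and leaving out single arrays 42. Signal over background limits what can be said of dim genes. With normexp correction the count of genes lower at least 2-fold at 24 h was 8, against 285. That alternative changed the spot intensity, the background correction and the offset together, and their parts were not tested apart.

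The count of genes called higher at 24 h, 736, was 448 without the filter and 417 with 6 arrays only. Leaving out 1 array gave 435 (without control replicate 1) to 662 (without control replicate 2), with 469 without control replicate 3 and 481 and 446 without loaded replicates 2 and 3. Fewer arrays, or more genes tested, lower the power of these settings by construction. The count of 3257 genes called lower at 24 h became 1922 with quantile normalization and 2008 with cyclic loess; 2536 and 2570 of the 3993 calls kept their direction there and 0 of the limma calls reversed, and the cause was not tested. Both gene counts of the other comparisons stayed within 1.5 times in all alternatives. With the replicate number as a block (replicate block), limma called 731 higher and 3469 lower at 24 h, 8263 and 7276 between 24 h and 7 d, and 6911 and 7244 at 7 d against the control. Same-number arrays of the 24 h groups correlated at 0.0535 to 0.107 after removal of group means, and arrays of other numbers at -0.0865 to -0.00939. The own number was the best match in 3 of 3 cases there. It was so in 2 of 3 between the loaded groups and in 1 of 3 between the control and 7 d. The number also marks the position on the slide, so a shared experiment and position cannot be told apart, and no pairing was assumed.

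The called lists (10, 13 and 12) fell to 1, 0 and 0 by camera with an estimated correlation and rose to 18, 28 and 26 with fry, which tests another question. At 24 h they numbered 6 to 14 with 1 array left out, the 6 without control replicate 2 and the 14 without control replicate 3. Cyclic loess ended the calls of the lysosome (adjusted p = 0.179) and fatty acid (0.0985) lists there. Between 24 h and 7 d they numbered 8 with median centring, 10 with quantile normalization and 8 to 13 with 1 array left out, the 8 without loaded 24 h replicate 2 or without 7 d replicate 2. Median centring ended the calls of the mitotic, hypoxia, heat shock, matrix and ribosomal lists, quantile normalization and cyclic loess those of the hypoxia, heat shock and ribosomal lists, and the replicate block that of the matrix list (0.0527). At 7 d against the control they numbered 7 with quantile normalization. The NRF2 call was lost with cyclic loess (0.0516) and the replicate block (0.0525), and that of TGF-beta with normexp correction (0.085) and the replicate block (0.0514). Against random lists matched on brightness, the medians of called lists lay at percentiles 51.5 (lysosome) and 94.5 (metallothioneins) at 24 h and 86.1 (ribosomal proteins) between 24 h and 7 d; those of ribosomal proteins lay at 98.2 in the other comparisons, and all others were under 1 or over 99. The ribosomal protein list between 24 h and 7 d turned its direction with quantile normalization (adjusted p = 0.835, against 0.0433). The cause was not tested. The count of 720 genes with the same direction at both times became 444 (without control replicate 1) to 775 (without loaded 24 h replicate 1), and that of 1995 with opposite directions 1315 (without control replicate 3) to 1993 (without loaded 24 h replicate 1).

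Of called genes with other probes, 8 of 567 at 24 h, 311 of 3605 between 24 h and 7 d and 282 of 3429 at 7 d against the control had another probe called in the opposite direction.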

Other observations

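The lists of LXR and retinoic acid targets, the brightness-matched random lists, cyclic loess and the tests of slide, sterol shortage, shared control arrays and brightness as the source of the opposite changes were chosen after results had been seen; the other tests were written down first. Of 9 measured retinoic acid targets, 4 fell at 24 h in the loaded cells (CYP26B1, DHRS3, RARRES1 and PLAAT4), with a median of -0.47, at percentile 0.28 of 10000 lists matched on brightness. DHRS3, which reduces retinal to retinol, changed by -1.50 ± 0.10 and PLAAT4 by -0.86 ± 0.09. Between 24 h and 7 d, 8 of the 9 rose and STRA6 fell, with a median of 1.53, and at 7 d against the 24 h control 8 rose and STRA6 fell, with a median of 1.02. RARB, a retinoic acid receptor that is its own target, was 3.24-fold higher at 7 d than at 24 h in loaded cells.

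Of 8 LXR targets, 7 rose between 24 h and 7 d in loaded cells, with a median of 0.79, and 6 were higher at 7 d than in the 24 h control, with a median of 0.81. ABCA1 was at least 15.3-fold higher at 7 d than at 24 h with nanoparticles, ABCG1 2.83-fold and NR1H3, which encodes an LXR, 1.76-fold. The retinoic acid list was written after the changes of CYP26B1 and DHRS3 were known, so it is no independent evidence of its direction, and ABCA1, ABCG1, MYLIP, SREBF1, LPCAT3, PLTP and NR1H3 were also in the fixed lipid list.

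More genes were called lower than higher at 24 h with nanoparticles, 3257 against 736. An additive background offset between the slides was argued against only where it is common to all spots and left after background subtraction. Probes never well above background changed by -0.689 intensity units, 13.6% of the -5.06 of the 7487 dimmest genes. Those probes were chosen for lying at background and stood near 0 after subtraction (median 0.878 in the controls). The intensities were not scaled between arrays, and an offset that subtraction had taken from those probes was not tested. A trend with brightness could still account for part: after cyclic loess 65.6% of the calls were lower, between bounds written before this value, but after other results, had been seen, while 1053 were higher and 2008 lower. Slide stays open, as 0 slides held more than 1 group and slide and group cannot be told apart. Loading with nanoparticles, with the sort that came with it, stays among the open explanations and was not tested apart from the slide.

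Cholesterol synthesis genes were higher at 24 h with nanoparticles, 21 of 25. A trend with brightness was argued against, since the list's median of 0.59 lay at percentile 100 of the lists matched on brightness. For a shift along the axis from the 24 h control to 7 d, the shared slope of all genes (-0.107) was taken out. This left 95.2% of the median (95% interval 90.9% to 113%, over resampled genes, which are not independent). As the list's median change at 7 d was -0.20, that slope could take out little. A shift of that size therefore leaves most of the rise unaccounted for, and a larger shift was not tested. A sterol shortage in loaded cells may be a candidate explanation, as the pathway is switched on when sterols are low; the LXR targets had a median of -0.158, at percentile 6.12 of the lists matched on brightness, with ABCG1 and MYLIP lower. That is 2 of 8 members, too few to decide. Both were also in the fixed lipid list, and the LXR list was chosen after results had been seen. Their falls are therefore no independent evidence. A difference between slides cannot be told apart from nanoparticle loading for these genes either.

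The changes at 24 h ran against those at 7 d, both measured from the same control arrays. Shared control arrays were argued against as the source, since they make a correlation positive (0.495 in simulated groups) and the measured one was r = -0.175. A trend between wide ranges of brightness was argued against as the only source, since r was below 0 in each range. Brightness still varied within each range, so a trend inside the ranges was not excluded. It was -0.110 within the 7487 dimmest genes, -0.271 within the 7487 of middle brightness and -0.201 within the 7487 brightest. Of the genes called lower at 24 h, 1952 were among the dimmest and 383 among the brightest. Part of the opposite calls may therefore still come from such a trend. Nanoparticle loading and time in culture stay open and were not tested, since the series has no 7 d control, and neither can be told apart from the slide here.

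Each comparison of 3 arrays with 3 allows 10 splits, too few for a share under 0.05. In each comparison 1 of the 10 splits, the real one, gave as many limma calls, with 3993, 15455 and 14036 genes for the real splits and 0 for the highest of the others. Every other split mixed arrays of both groups, which added the group difference to the spread. Their 0 calls therefore say nothing about the source of the difference.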
